A study of Streptococcus mutans UA159 with 16 samples.

How the data were processed

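RNA from Streptococcus mutans UA159, an oral bacterium that ferments sugars to acid, was measured on 16 spotted 2-colour arrays. Per the labels' protocols, the cells were kept in a fermentor under continuous flow at a dilution rate of 0.144 per h, with a 1% supply of glucose or maltose that did not limit growth, until the culture held a steady pH of 7 or 5. The arrays form 4 groups of 4 (glucose at pH 7, glucose at pH 5, maltose at pH 7, maltose at pH 5). On every array the sample carried Cy3 and a common reference, RNA of the same strain in mid-log growth, carried Cy5, per the labels' protocols. The dyes were never swapped. The labels do not say whether the replicates of a group were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

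Each array's file holds 1 integrated intensity per channel for each of 1947 genes, with a background intensity, flags and the position on the slide, per the file headers. The values show that background had been subtracted from the deposited intensities and that the 2 channels had been brought to nearly equal medians. The image software, the normalization and the averaging of spots are not given in the sources used here. The deposited series matrix holds log2 values, which equal the log2 ratio of channel A to channel B of the same array's file, with no further centring. Its column medians were 0.02, -0.01, 0.00255 and 0.03 for glucose at pH 7, 0.06, -0.05, 0 and 0.03 for glucose at pH 5, -0.03, -0.02, 0 and -0.08 for maltose at pH 7, and 0.0020, 0.0020, -0.04 and -0.03 for maltose at pH 5, each in replicate order. The file headers do not name the dye of each channel. Direction was therefore settled from the values: channel B intensities correlated more between groups than channel A intensities (mean r 0.859 against 0.743 across genes, higher in 93 of 96 pairs of arrays), so B was taken as the common reference and A as the sample.

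Median Cy3 intensity per array ranged from 7352 to 28037.5. Values with no spot found (14 to 236 per array, 974 over all arrays), overflow values (12) and values of 0 in both channels (13) were left out. Some values fell under more than 1 of these reasons, and 986 of 31152 values were missing. Spots flagged in 1 channel only and saturated spots were kept. In the log2 ratios as deposited, a smoothed trend on mean log2 intensity spanned 0.273 to 0.699 within an array, above the limit of 0.25 set in the plan, so each array was normalized with a global loess in limma 3.58.1 (R 4.3.3). No scaling between arrays was applied.

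A group means model was fitted to all 16 arrays with limma's lmFit and eBayes, and 5 contrasts were tested with the two-sided moderated test: pH 5 against pH 7 in each sugar, maltose against glucose at each pH, and the difference of the pH effect between the sugars. A gene needed a value on at least 3 of the 4 arrays of every group in the contrast. Adjusted p-values are Benjamini-Hochberg values within a contrast, and a gene was called at an adjusted p under 0.05. There were 26 gene lists (named with their results in the report). All were fixed by locus tag except those of the 24 aminoacyl-tRNA synthetase and the 51 ribosomal protein genes, which were taken from the product text. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over the 26 lists of a contrast. Missing values were filled with the group mean for these list tests only.

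The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, in each comparison of groups, the 8 largest rises and the 8 largest falls among called genes whose arrays do not overlap between the groups. It adds up to 3 called members of each list with the largest changes, and takes the 5 largest differences in each direction for the difference of the pH effect. Genes named outside the rule are said to be so. Gene symbols come from the files or from the RefSeq table of assembly ASM746v2, which matched 1837 of 1947 loci and was used only for names and for which genes are neighbours. On simulated data with the real arrays' spread, limma recovered 89.6%, 85.1%, 85.1% and 92.5% of genes changed 4-fold in the 4 comparisons of groups, in the order given above, and 47.8% in the difference of the pH effect. Genes changed 2-fold were recovered at 25.4%, 43.3%, 38.8%, 35.8% and 4.48%. Of the calls on these data 21 of 162, 17 of 167, 6 of 155, 49 of 199 and 8 of 95 were wrong (13.0%, 10.2%, 3.87%, 24.6% and 8.42%), more than the nominal 5% in all but sugar at pH 7. A fit to the groups compared alone gave 10.5%, 6.49%, 4.85%, 7.69% and 8.42%. With no change simulated, 5 genes were called for sugar at pH 5 and none in the others. The simulated noise was drawn for each gene apart, without the effects of slide position that genes shared on the real arrays. This may make the recovered and wrong shares too favourable. The simulated spread of a gene in a group was its SD over that group's 4 arrays. Such SDs differ between groups partly by chance, which may make the wrong shares of the fit to all arrays too high. The shares come from a single simulated data set per comparison and may thus err in either direction.

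The alternatives were normexp background correction, the ratios as deposited, median centring, loess within each subgrid of the slide (print-tip loess), scaling between arrays, flagged spots kept, the dimmest 25% of genes left out, a fit to the groups compared alone, array weights, an intensity trend in eBayes, the replicate number as a block, the series matrix values and each array left out in turn. Another 3 were added after the data were seen. The number of arrays limits the precision: the median SE of a log2 change was 0.42 in glucose and 0.41 in maltose for the pH comparisons.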

Results

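Streptococcus mutans UA159 was held in continuous culture at a steady pH of 7 or 5 on glucose or maltose, and its RNA was compared with a common reference on 16 arrays, 4 for each combination of sugar and pH. The arrays address which transcripts the bacterium adjusts to acid, which to the sugar, and whether its adjustment to acid differs between the sugars. Each array gave a log2 ratio of sample to reference for up to 1947 genes, and the median Cy3 intensity per array ranged from 7352 to 28037.5. The Cy3 signal was under the spot background for 56.0%, 54.5%, 70.3% and 24.9% of genes on the arrays of maltose at pH 5, in replicate order, and for at most 44.4% on any other array. Here and below this signal is what was left after background had been subtracted. A value under the background is thus low relative to it, and does not by itself show that no signal was present. Across genes, which are not independent replicates, the lowest, median and highest correlation between the arrays of a group were 0.578, 0.736 and 0.862 for glucose at pH 7, 0.416, 0.524 and 0.698 for glucose at pH 5, 0.816, 0.822 and 0.890 for maltose at pH 7, and 0.450, 0.599 and 0.792 for maltose at pH 5. The median SD of a gene's log2 ratio was 0.41, 0.60, 0.38 and 0.59 in the same order, so the arrays of both pH 5 groups lay further apart than those of the pH 7 groups. Values below are log2 changes with their SE from the fit to all arrays, with 4 arrays per group unless another n is given. A gene is said to have risen or fallen where its adjusted p (limma) was under 0.05.

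The genes lay in 48 subgrids on the slide (12 by 4, with 39 to 43 genes each), and the log2 ratios differed between subgrids. In the corner subgrid (row 1, column 1) the median log2 ratio was 1.52 to 2.17 on the arrays of maltose at pH 7, -0.04 to 1.33 for glucose at pH 7, 0.47 to 1.23 for glucose at pH 5 and 0.64 to 1.17 for maltose at pH 5. Subgrid accounted for 21.6% of the variance of the log2 change across genes for pH in glucose, 21.9% for pH in maltose, 46.6% for sugar at pH 7, 24.3% for sugar at pH 5 and 41.8% for the difference of the pH effect. The highest share from 1000 random assignments of genes to subgrids was 5.33% in any of these comparisons. Loess within each subgrid (print-tip loess) removes such differences. The number of genes it called, the named genes whose calls it ended and the lists it moved across the threshold are given with each comparison. Each of its fits rests on 39 to 43 genes and can also take up real changes. A smaller change under it thus need not mean that position enlarged the main value. Of the 29, 66, 7, 51 and 10 named genes, in the order above, it kept the calls of 19, 51, 3, 40 and 5. Subtracting subgrid medians after the global loess, added after the data were seen, kept 21, 53, 3, 43 and 7.

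**Figure D1:**
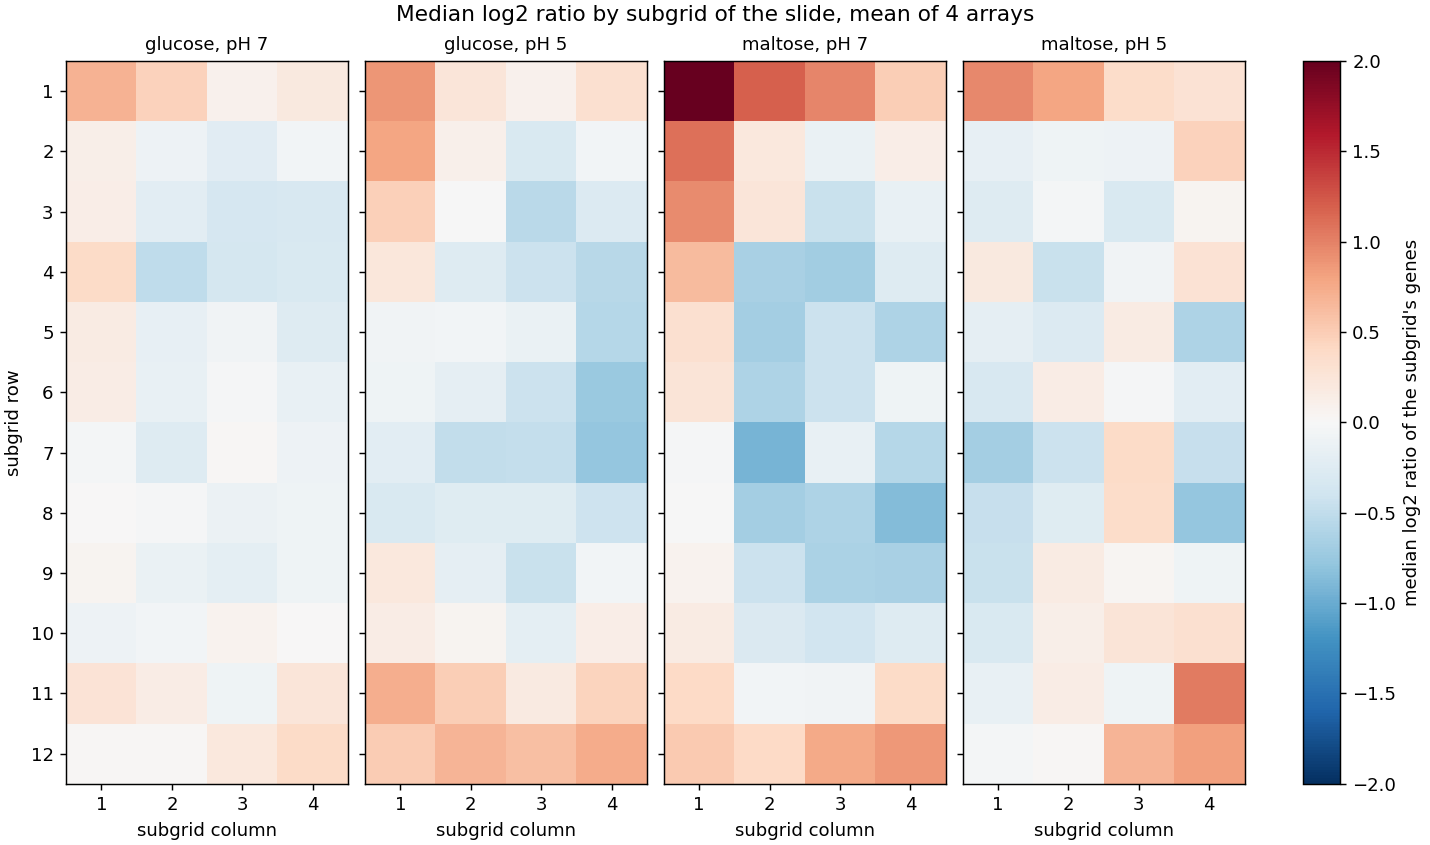
Median log2 ratio of each of the 48 subgrids at its place on the slide (12 by 4), as the mean of the 4 arrays of each group. The corner subgrid (row 1, column 1) was highest in maltose at pH 7, where its 4 arrays lay at 1.52 to 2.17.

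The question for glucose was which genes change when cells that grow on it are held at pH 5 in place of pH 7. Several genes of the bacteriocin region, which encodes small peptides that kill other bacteria, and the thiol peroxidase gene tpx rose. The fructosyltransferase gene ftf, whose enzyme builds fructan from sucrose, fell. SMU.1914c, the mutacin V gene, rose by 4.93 ± 0.72 (30.4-fold, adjusted p = 0.00106), from a mean log2 ratio of -1.37 (SD 0.72, n = 4) to 3.56 (SD 1.88, n = 4). Its background-subtracted Cy3 signal lay under the spot background on 3 of 4 arrays at pH 7, so this fold is set against a baseline low relative to background. Among the genes of an array its mean Cy3 percentile there was 54.5. tpx rose 10.2-fold (3.36 ± 0.54), and ftf fell 8.47-fold (-3.08 ± 0.57) from 3.11 (SD 0.11, n = 4) to 0.03 (SD 1.52, n = 4). Among the falls were SMU.1895c (-4.20 ± 0.49, adjusted p = 5.3e-05) and SMU.1896c (-3.35 ± 0.33, adjusted p = 1.3e-05), in the same chromosomal region as the genes that rose. Print-tip loess made the rise of tpx 2.89-fold (1.53) and that of SMU.1914c 15.3-fold (3.94), and the fall of SMU.1895c 8.45-fold (-3.08). It moved 16 of the 29 named genes of this comparison by more than 1.5-fold, 15 of them to a smaller change. With subgrid medians subtracted instead, tpx rose 5.78-fold and SMU.1914c 28.9-fold, and SMU.1895c fell 14.8-fold. Of 1878 genes tested, 65 changed, 41 rising and 24 falling, and 64 of them changed at least 2-fold. The count was 32, 21 and 31 without replicates 1, 2 and 3 of glucose at pH 7. It was 119 and 25 without replicates 2 and 4 of glucose at pH 5, 43 and 42 without replicates 2 and 4 of maltose at pH 7, and 113 without replicate 1 of maltose at pH 5. With normexp background correction it was 13, in a fit to the groups compared alone 16, and with scaling between arrays 136.

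Other genes with large rises were SMU.1913c (3.49 ± 0.84), SMU.1906c (3.47 ± 0.78), the mutacin IV gene nlmB (3.28 ± 0.86), SMU.602 (3.07 ± 0.60), SMU.925 (3.05 ± 0.78) and SMU.600c (2.71 ± 0.47). SMU.961 (-3.36 ± 0.70), SMU.2146c (-2.88 ± 0.62), the isocitrate dehydrogenase gene icd (-2.21 ± 0.39), the metal transport gene sloA (-1.90 ± 0.49) and SMU.277 (-1.85 ± 0.39) fell. SMU.602 and levD lay in the dimmest 10% of Cy3 values on every array of at least 1 of the groups. The Cy3 signal of 9 of the 29 named genes (SMU.1913c, SMU.1906c, SMU.602, SMU.600c, SMU.1895c, icd, levD, levG and levE) was under the spot background on every array of 1 group, so the sizes of their changes rest on weak signal there.

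Of the gene lists, 4 shifted upward past the threshold in glucose at pH 5. The F-type ATPase, which pumps protons out of the cell, had 3 of 8 measured genes rise and none fall (6 adjusted over the list alone), with atpG up 3.41-fold (1.77 ± 0.37), atpA 2.38-fold and atpD 2.34-fold. All 8 changes were positive, with a median of 1.09 and a list adjusted p of 7.6e-05 (adjusted p = 0.258 with an estimated correlation). Sucrose, fructose and fructan use had 4 of 12 rise (5 adjusted over the list alone), with a median of 0.83. They included the transporter genes levD (3.74 ± 0.83), levG (2.57 ± 0.66) and levE (2.25 ± 0.55), and the list adjusted p was 0.00499 (adjusted p = 0.177 with an estimated correlation). Among the oxidative stress genes only tpx rose of 7 measured (3 adjusted over the list alone), with a median of 0.69 and a list adjusted p of 0.00777 (adjusted p = 0.258 with an estimated correlation). No purine synthesis gene passed the test over all genes and 2 of 10 did adjusted over the list alone. All 10 changes were positive, the median was 0.89 and the list adjusted p was 0.00804 (adjusted p = 0.491 with an estimated correlation).

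The other 22 lists did not pass, with adjusted p-values from 0.0532 to 0.957. Bacteriocins had 3 of 10 genes rise and 1 fall (6 and 2 adjusted over the list alone), with a median of 2.30. Glucan and adhesin genes had 2 of 11 fall (4 fell and 1 rose adjusted over the list alone), among them ftf and the glucosyltransferase gene gtfD (-1.30 ± 0.31), with a median of -0.23. Of 24 aminoacyl-tRNA synthetase genes, pheT (1.65) and ileS (1.49) rose (2 adjusted over the list alone, median 0.07). For branched-chain amino acids, ilvC alone of 15 rose (1.58 ± 0.42, 3 adjusted over the list alone, median 0.13). Of the citrate pathway and glutamate genes, icd alone of 8 fell (3 fell and 1 rose adjusted over the list alone, median 0.07). A single gene fell in each of fatty acid biosynthesis (fabH of 13, -1.74, 1 adjusted over the list alone, median -0.22), pyrimidine synthesis (pyrP of 9, -1.30, 1 adjusted over the list alone, median -0.37) and the ribosomal proteins (rpsB of 51, 2.00-fold, 0 adjusted over the list alone, median -0.04).

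No member was called in glucose for malolactic fermentation (3 measured, median 0.43), the agmatine deiminase system (3, -0.07), chaperones and proteases (15, -0.15), maltose, maltodextrin and glycogen use (13, -0.43), glucose and mannose uptake (6, -0.07) and the msm operon (8, 0.35). Nor was one called for lactose and galactose use (11, 0.02), cellobiose, trehalose, mannitol and sorbitol use (12, -0.21), glycolysis and lactate formation (11, -0.09), competence (15, 0.22), lipoteichoic acid D-alanylation (4, -0.37), the mutanobactin cluster (8, 1.22) and CRISPR-associated genes (14, -0.37). The same held for pyruvate use other than lactate (15, -0.19), where 1 gene rose adjusted over the list alone. The median and mean had opposite signs for glucose and mannose uptake (mean 0.01, tested downward), pyruvate use (mean 0.0072, tested upward) and the citrate pathway (mean -0.23, tested downward). Print-tip loess called 73 genes, 36 of them shared with the 65, and among the 29 named genes (7 called under every one of the 31 alternatives) it ended the calls of nlmB (2.43), SMU.925 (1.67), icd (-1.22), sloA (-0.63), SMU.277 (-0.46), atpA (0.64), fabH (-0.59), pheT (0.79) and ileS (0.55), and of rpsB, whose fall was larger (-1.38). A fit to the groups compared alone kept the calls of 11 of the 29, and ended those of all 3 ATPase genes and of levD, levG and levE. Print-tip loess also ended the list call for oxidative stress (adjusted p = 0.135) and scaling between arrays that for purine synthesis (adjusted p = 0.0552). Print-tip loess brought fatty acid biosynthesis (0.00717) and lipoteichoic acid D-alanylation (0.0263) past the threshold. The mutanobactin cluster, at 0.0532, passed under 14 of the 31 alternatives, among them print-tip loess (0.00717), scaling between arrays (0.00268) and array weights (0.0323). It also passed without replicates 2 and 4 of glucose at pH 7 (0.0277 and 0.0226), replicate 3 of glucose at pH 5 (0.00737) and replicates 2 and 3 of maltose at pH 7 (0.0426 and 0.0477). Bacteriocins passed with array weights (0.00739) and without replicate 1 of glucose at pH 5 (0.0239), and branched-chain amino acids without replicate 2 of that group (0.014). Without its replicate 3, maltose, maltodextrin and glycogen use and pyrimidine synthesis passed (0.0417 each), as they did with scaling (0.0144 and 0.0481), and ribosomal proteins passed with array weights (0.0347).

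For maltose, the same question was asked of cells that grew on the glucose disaccharide. Genes of the bacteriocin region had the largest rises, and the bifunctional alcohol and aldehyde dehydrogenase gene adhE, whose enzyme turns acetyl-CoA into ethanol, fell most. SMU.1913c rose by 7.48 ± 0.84 (178-fold, adjusted p = 6.6e-06), from -3.77 (SD 0.99, n = 4) to 3.71 (SD 1.07, n = 4), and SMU.1914c rose 111-fold (6.79 ± 0.72). At pH 7 the Cy3 signal lay under the spot background on 4 of 4 arrays for SMU.1913c and on 3 of 4 for SMU.1914c, so both folds are set against a weak baseline, and the log2 change of SMU.1913c ranged from 6.76 to 10.2 over the alternatives. adhE fell 52.1-fold (-5.70 ± 0.50, adjusted p = 1.3e-06), from 5.52 (SD 0.47, n = 4) to -0.18 (SD 0.78, n = 4). All measured genes for the uptake of glucose and mannose fell, among them manM (-3.12 ± 0.31) and manN (-2.81 ± 0.27) of the main glucose transporter. Of 1933 genes tested, 323 changed, 138 rising and 185 falling, and 305 of them changed at least 2-fold. There were 105 rises and 113 falls without replicate 4 of maltose at pH 7, 96 and 121 without its replicate 2, and 142 of each without replicate 2 of maltose at pH 5. Print-tip loess called 332 genes, with 175 in common. It moved 33 of the 66 named genes by more than 1.5-fold, 28 of them to a smaller change, with adhE at -4.81, SMU.1914c at 6.14, manM at -1.72 and manN at -2.19. With subgrid medians subtracted instead, the changes of these genes were -5.17, 6.42, -2.59 and -2.45.

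Further large rises were those of SMU.1906c (6.46 ± 0.78), the mutacin gene nlmA (5.78 ± 0.68), SMU.423 (5.66 ± 0.76), SMU.602 (5.62 ± 0.59), SMU.1908c (5.24 ± 0.92) and SMU.1705 (4.70 ± 0.47). SMU.941c (-4.89 ± 0.73), SMU.2146c (-4.61 ± 0.62), SMU.940c (-4.06 ± 0.61), the trehalose hydrolase gene treA (-3.98 ± 0.55), the murein hydrolase regulator gene lrgA (-3.97 ± 0.73), SMU.2147c (-3.97 ± 0.52) fell. SMU.252 fell from a mean of 3.31 to -0.69 (SD 0.88 and 0.85, n = 4 each). SMU.941c, treA and comD lay in the dimmest 10% of Cy3 values on every array of at least 1 of the groups. The Cy3 signal of 19 of the 66 named genes was under the spot background on every array of 1 group, so the sizes of their changes rest on weak signal there. They were SMU.1913c, SMU.1906c, SMU.602, SMU.941c, SMU.2146c, SMU.940c, treA, mleS, oxdC, glgD, glgC, manN, treB, srlD, spaP, gtfD, icd, comD and mubG.

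**Figure D2:**
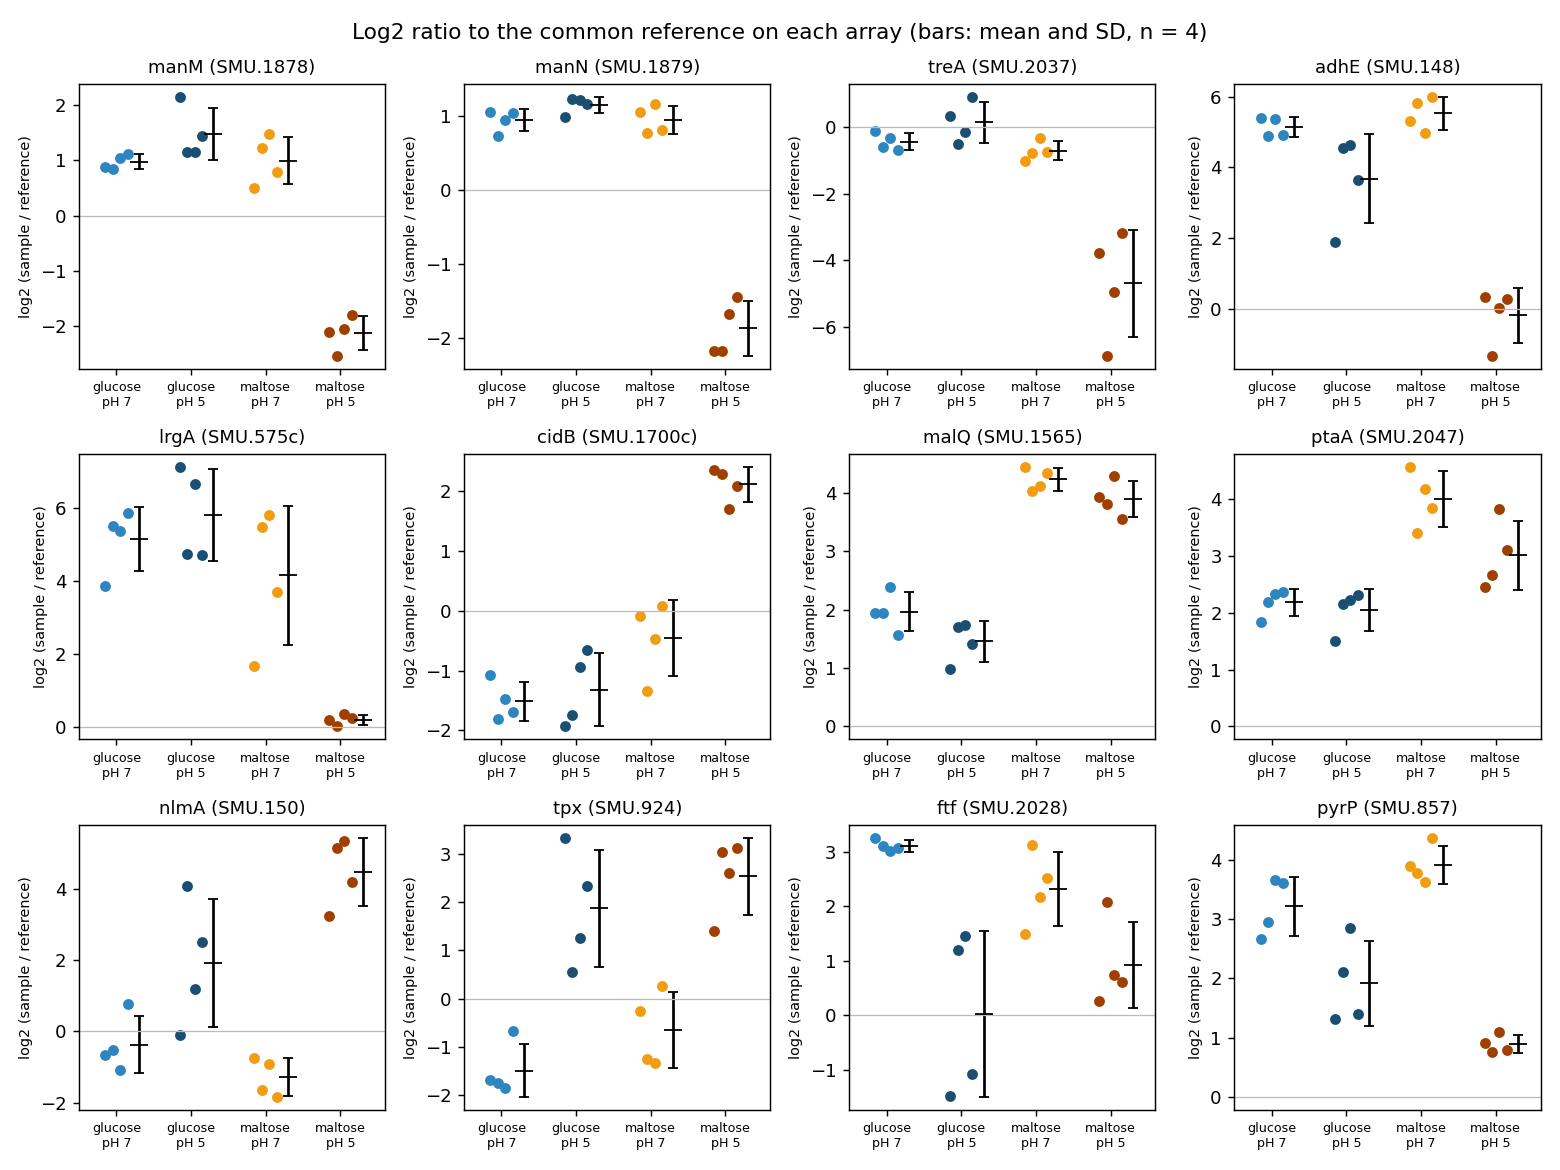
Log2 ratio of sample to reference for 12 genes on each of the 16 arrays, with the mean and SD of each group (n = 4). The 4 arrays of maltose at pH 5 stand apart for manM (mean -2.12) and treA (mean -4.70), while malQ lies higher in maltose at both pH values (means 4.23 and 3.89).

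In maltose, 7 lists passed the threshold. Glucose and mannose uptake fell in all 6 measured genes (6 adjusted over the list alone), including the glucokinase gene glk (-2.45 ± 0.34). Its median was -2.14 and its adjusted p 1.5e-07, and it also passed with an estimated correlation (adjusted p = 0.00453). Of the oxidative stress genes, 6 of 8 rose and none fell (6 adjusted over the list alone), led by tpx (9.08-fold), the superoxide dismutase gene sodA (6.91-fold) and the peroxidase gene ahpC (5.95-fold). The median was 2.40 and the adjusted p 2.9e-05 (adjusted p = 0.0538 with an estimated correlation). With print-tip loess tpx rose 2.25-fold, sodA 2.00-fold and ahpC 3.99-fold, and the median change of the list was 2.39-fold in place of 5.29-fold. With subgrid medians subtracted instead, tpx rose 13.2-fold, sodA 5.35-fold and ahpC 3.90-fold. These corrections thus differed for tpx and sodA, and the share of their rise that came from slide position cannot be told. Bacteriocins rose in 6 of 10 genes and fell in 1 (the same counts adjusted over the list alone), with a median of 3.85 and an adjusted p of 2.2e-04 (adjusted p = 0.244 with an estimated correlation). Their median was 5.12 without replicate 1 of maltose at pH 5. The F-type ATPase had 2 of 8 rise, atpD (1.44) and atpA (1.13), and 7 adjusted over the list alone. Its median was 0.96 and its adjusted p 0.00142 (adjusted p = 0.244 with an estimated correlation).

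Fatty acid biosynthesis, which makes the acyl chains of the membrane, had 5 of 13 genes fall (6 adjusted over the list alone), among them accA (-1.76), accD (-1.37) and accC (-1.35). Its median was -0.79 and its adjusted p 0.00647 (adjusted p = 0.244 with an estimated correlation). Maltose, maltodextrin and glycogen use had 5 of 14 fall (7 fell and 1 rose adjusted over the list alone), with the glycogen synthesis genes glgD (5.70-fold), glgC (5.09-fold) and glgA (5.06-fold) ahead (2.41-, 6.27- and 3.59-fold with print-tip loess). Its median was -0.90 and its adjusted p 0.0122 (adjusted p = 0.33 with an estimated correlation). For branched-chain amino acids 4 of 15 rose and 1 fell (6 and 1 adjusted over the list alone), with ilvN at 2.22, livH at 1.72 and ilvB at 1.32. The median was 0.63 (0.02 with print-tip loess) and the adjusted p 0.0495 (adjusted p = 0.33 with an estimated correlation).

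The other 19 lists had adjusted p-values from 0.0665 to 0.916 in maltose. Cellobiose, trehalose, mannitol and sorbitol use had 4 of 12 fall and 1 rise (5 and 2 adjusted over the list alone, median -0.94), with treA, treB (-2.25, n = 3 at pH 5) and srlD (-1.61, n = 3 at pH 5) among the falls. Of the aminoacyl-tRNA synthetase genes, 6 of 24 fell and 1 rose (6 and 2 adjusted over the list alone, median -0.71), with metG at -1.73, thrS at -1.54 and aspS at 1.76. Pyruvate use other than lactate had 3 of 15 rise and 3 fall (4 and 5 adjusted over the list alone, median -0.35), with adhE and the acetate kinase gene ackA (-2.18) among the falls, beside the formate lyase gene pfl (-1.47). Chaperones and proteases had 3 of 15 fall and 1 rise (3 and 2 adjusted over the list alone, median 0.10), with the repressor gene hrcA at -2.91, clpC at -1.96 and ftsH at 1.86. Pyrimidine synthesis had 2 of 9 fall and 1 rise (4 and 1 adjusted over the list alone, median -0.78), with pyrP at -3.03, pyrD at -1.28 and pyrB at 1.17. Ribosomal proteins had 3 of 51 fall (1 adjusted over the list alone, median -0.39), namely rpsA (-1.69), rpsB (-0.94) and rpsE (-0.90).

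Glucan and adhesin genes had 2 of 11 rise and 1 fall (the same counts adjusted over the list alone, median 0.08), with the surface adhesin gene spaP at 2.64, the dextranase gene dexA at 1.41 and gtfD at -1.36. Sucrose, fructose and fructan use had 2 of 12 fall (2 adjusted over the list alone, median -0.60), the sucrose genes scrA (-2.04) and scrB (-1.86). In malolactic fermentation 2 of 3 fell (2 adjusted over the list alone, median -1.31), mleS (-1.37, n = 3 at pH 5) and oxdC (-1.31). For lactose and galactose use lacB (1.28) and lacX (1.16) of 12 rose (3 adjusted over the list alone, median 0.20), and for glycolysis gapN (1.63) and pyk (0.98) of 11 rose (2 adjusted over the list alone, median 0.27). Competence had comD, the sensor gene of the competence peptide (3.72 ± 0.55), and comFA (1.33) rise of 17 (2 adjusted over the list alone, median 0.31). In the citrate pathway gdhA (2.88) rose and icd (-2.22) fell of 8 (1 and 2 adjusted over the list alone, median -0.20). mubG (3.16) rose in the mutanobactin cluster of 8 (1 adjusted over the list alone, median 0.32), and SMU.1764c (-1.52) fell among 14 CRISPR-associated genes (1 adjusted over the list alone, median -0.55).

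None of the measured genes was called in maltose for the agmatine deiminase system (4, median 0.18), the msm operon (7, -0.20), purine synthesis (10, 0.39) and lipoteichoic acid D-alanylation (4, 0.30). The median was positive and the mean negative, as was the test's direction, for the agmatine deiminase system (mean -0.04) and chaperones (mean -0.16). With print-tip loess the change of oxdC was 0.32 in place of -1.31, and the calls of atpD (0.29), mleS (-0.08), accA (-0.42), lacB (0.49), lacX (0.60), srlD (-0.46), dexA (0.86), pyk (0.58), pyrB (0.23), comFA (0.52), SMU.1764c (-0.54), aspS (0.99) and thrS (-0.53) ended. So did that of rpsB, whose fall was larger (-1.15), while 43 of the 60 named genes that could be tested under all 31 alternatives were called under each. The list call for maltose, maltodextrin and glycogen use ended with normexp background correction (adjusted p = 0.101) and with scaling between arrays (0.0831), and that for branched-chain amino acids under 18 of the 31 alternatives. For the latter the adjusted p was 0.0506, 0.051 and 0.0566 without replicates 1, 2 and 3 of glucose at pH 7, 0.0517 and 0.0513 without replicates 3 and 4 of glucose at pH 5, and 0.103, 0.0728 and 0.052 without replicates 1, 2 and 3 of maltose at pH 5. Ribosomal proteins passed the threshold with print-tip loess (0.00675), with scaling (0.014) and without replicates 2 and 3 of maltose at pH 5 (0.0343 and 0.0112), and pyrimidine synthesis with print-tip loess (0.0467). Cellobiose and related sugars passed with array weights (0.0481), without replicate 4 of glucose at pH 7 (0.0475) and without replicate 1 of maltose at pH 7 (0.0477).

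Maltose against glucose at pH 7 asked which genes respond to the sugar in the absence of acid. The 4-alpha-glucanotransferase gene malQ, whose enzyme breaks down maltose and maltodextrins, rose 4.83-fold (2.27 ± 0.29, adjusted p = 0.000513), from 1.96 (SD 0.33, n = 4) in glucose to 4.23 (SD 0.20, n = 4) in maltose. The transporter gene ptaA (SMU.2047) rose 3.53-fold (1.82 ± 0.35, adjusted p = 0.0326). Of 1920 genes tested, 7 changed, 6 rising and 1 falling, all at least 2-fold. The others were hisC (3.14 ± 0.62, n = 3 in maltose), SMU.613 (2.60 ± 0.55), recJ (2.60 ± 0.53), thiD (2.16 ± 0.44) and the ribosomal protein gene rplX (-1.68 ± 0.34). hisC lay in the dimmest 10% of Cy3 values on every array of 1 of the groups. hisC, SMU.613, recJ and thiD had Cy3 signal under the spot background on every array of glucose. In maltose this held on 2 of 3 arrays for hisC and on 3 of 4 for SMU.613, recJ and thiD, so signal was low on both sides. The count was 4, 1, 13 and 2 without replicates 1, 2, 3 and 4 of glucose at pH 7, and 11 and 1 without replicates 1 and 3 of glucose at pH 5. It was 1, 2 and 1 without replicates 1, 2 and 4 of maltose at pH 7, and 14 without replicate 1 of maltose at pH 5. The fit to all arrays also took its spread from the pH 5 arrays, which lay further apart. A fit to the groups compared alone called 21 genes and array weights 248. Normexp background correction called 1 and scaling between arrays 2. The count of 7 thus depends strongly on the processing and on how the spread is estimated.

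At pH 7, 3 lists passed the threshold between the sugars. Maltose, maltodextrin and glycogen use had 2 of 14 genes rise, malQ and ptaA, and 7 rise with 1 fall adjusted over the list alone. Its median was 0.93 and its adjusted p 0.00187 (adjusted p = 0.493 with an estimated correlation). Glucan and adhesin genes had none of 11 called over all genes and 3 fall with 1 rise adjusted over the list alone. Their median was -0.69 and the adjusted p 0.00674 (adjusted p = 0.169 with an estimated correlation). Of 51 ribosomal protein genes rplX alone fell, over all genes and adjusted over the list alone, with a median of -0.23 and an adjusted p of 0.0366 (adjusted p = 0.924 with an estimated correlation). That list lost its call without replicate 1, 2 or 3 of glucose at pH 7 (adjusted p = 0.18, 0.126 and 0.146), replicate 3 of maltose at pH 7 (0.0755) and replicate 2 of maltose at pH 5 (0.0514).

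The other 23 lists had no called member at pH 7 and adjusted p-values from 0.057 to 0.95. They were the F-type ATPase (8, median -0.31), malolactic fermentation (3, 0.70, 1 rose adjusted over the list alone), the agmatine deiminase system (4, 0.09), fatty acid biosynthesis (13, -0.34), chaperones and proteases (15, -0.0020, 1 rose adjusted over the list alone), oxidative stress (7, 0.07) and glucose and mannose uptake (6, 0.01). Further ones were the msm operon (7, 0.01), lactose and galactose use (11, -0.13), cellobiose, trehalose, mannitol and sorbitol use (12, -0.12) and sucrose, fructose and fructan use (12, -0.15). They were also glycolysis (11, 0.06), pyruvate use (15, -0.12), the citrate pathway (8, -0.13), branched-chain amino acids (15, 0.01), purine synthesis (10, 0.25), pyrimidine synthesis (9, 0.23) and competence (17, -0.10). The last of them were bacteriocins (10, -0.39, 1 fell adjusted over the list alone), lipoteichoic acid D-alanylation (4, -0.41), the mutanobactin cluster (8, 0.50), CRISPR-associated genes (14, 0.24, 1 fell adjusted over the list alone) and aminoacyl-tRNA synthetases (24, 0.05, 2 rose adjusted over the list alone). The median and mean had opposite signs for chaperones (mean 0.10), glucose and mannose uptake (-0.06), cellobiose and related sugars (0.13), branched-chain amino acids (-0.07) and competence (0.03), with the test on the side of the mean, and glycolysis tested downward with a mean of 0.02. Print-tip loess called 6 genes, 3 of them (malQ, ptaA and hisC, the last at 1.93 in place of 3.14) among the 7. It ended the calls of SMU.613 (0.91), recJ (1.14), thiD (0.69) and rplX (-1.46, about as large as before), and moved the ribosomal protein list to an adjusted p of 0.0555. Scaling between arrays ended the calls of malQ (adjusted p = 0.136) and of the maltose and ribosomal lists (adjusted p = 0.48 and 0.753), and none of the 7 genes was called under every alternative run for it. Subtracting subgrid medians ended the list call for glucan and adhesin genes (adjusted p = 0.0688) and brought the F-type ATPase past the threshold (0.0235). Scaling did so for the mutanobactin cluster (0.000728), and leaving out replicate 2 of maltose at pH 7 for malolactic fermentation (0.0411).

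Maltose against glucose at pH 5 asked the same of acid cultures. The murein hydrolase regulator genes lrgA and lrgB, which take part in control of cell lysis, fell, while cidA and cidB, their counterparts at another locus, rose. lrgA fell 49.4-fold (-5.63 ± 0.73, adjusted p = 6.4e-05), from 5.82 (SD 1.27, n = 4) in glucose to 0.19 (SD 0.14, n = 4) in maltose, and cidB rose 10.8-fold (3.43 ± 0.36, adjusted p = 5.6e-06), from -1.32 (SD 0.61, n = 4) to 2.11 (SD 0.29, n = 4). manM fell 12.1-fold (-3.59 ± 0.31, adjusted p = 5.9e-07), from 1.47 (SD 0.47, n = 4) to -2.12 (SD 0.31, n = 4), and malQ rose 5.43-fold (2.44 ± 0.29). Of 1889 genes tested, 219 changed, 94 rising and 125 falling, and 212 of them changed at least 2-fold. There were 49 rises and 105 falls without replicate 4 of maltose at pH 5, and 56 and 104 without its replicate 3. The shares of wrong calls on simulated data may err in either direction. In this comparison 24.6% of such calls were wrong (49 of 199), against 7.69% in a fit to the groups compared alone. That fit called 58 genes here, 57 of them among the 219, and 31 of the 51 named genes, lrgA, lrgB, cidA, cidB, manM and malQ among them. Print-tip loess called 199 genes, with 118 in common. Under it manM fell by -2.17 and cidB rose by 2.37, and 25 of the 51 named genes moved by more than 1.5-fold, 23 of them to a smaller change. With subgrid medians subtracted instead, the changes of manM and cidB were -3.38 and 2.80.

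Besides these, SMU.602 (3.87 ± 0.60), cidA (2.78 ± 0.46), malX (2.75 ± 0.55), the glucosidase gene gla (2.41 ± 0.36), SMU.995 (2.41 ± 0.33) and SMU.1903c (2.36 ± 0.56, n = 3 in glucose) rose. The log2 ratio of malX was -1.39 on replicate 1 of glucose and 1.27 to 1.56 on the other glucose arrays, which enlarges its rise. Among the other falls were treA (-4.84 ± 0.55), lrgB (-3.99 ± 0.54), adhE (-3.86 ± 0.51), the aldehyde dehydrogenase gene gabD (-3.78 ± 0.35), the ribosomal protein gene rpsQ (-3.51 ± 0.64) and the phosphoglucomutase gene pgmA (-3.37 ± 0.30). treA and gtfC lay in the dimmest 10% of Cy3 values on every array of at least 1 of the groups. The Cy3 signal of 10 of the 51 named genes (cidB, treA, rpsQ, glgD, manN, treB, pfkB, levF, gtfC and mubG) was under the spot background on every array of 1 group, and that of lrgA on 3 of 4 arrays in maltose.

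At pH 5, 6 lists passed the threshold between the sugars. Glucose and mannose uptake fell in all 6 measured genes (6 adjusted over the list alone), with manM, manN (8.10-fold) and manL (7.05-fold) ahead. Its median was -2.19 (-1.59 with print-tip loess) and its adjusted p 2.7e-09, and it also passed with an estimated correlation (adjusted p = 0.00177). Sucrose, fructose and fructan use fell in 7 of 12 genes (8 adjusted over the list alone), among them pfkB (-2.96), levF (-2.87) and the fruA of SMU.872 (-2.86). Its median was -1.81 (-1.01 with print-tip loess, -3.03 with normexp background correction) and its adjusted p 1.2e-05, and it passed with an estimated correlation too (adjusted p = 0.00936). Of the oxidative stress genes 4 of 8 rose and none fell (4 adjusted over the list alone), including the glutathione reductase gene of SMU.838 (1.69), trxB (1.64) and ahpC (1.54). All 8 changes were positive, with a median of 1.11 and an adjusted p of 0.00103 (adjusted p = 0.132 with an estimated correlation).

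Fatty acid biosynthesis at pH 5 had 4 of 13 genes lower and 1 higher in maltose (6 and 1 adjusted over the list alone), with accA (-2.14), accC (-2.12) and accD (-1.73) ahead. Its median was -0.91 and its adjusted p 0.00115 (adjusted p = 0.132 with an estimated correlation). Ribosomal proteins had 16 of 51 fall and 1 rise (19 and 3 adjusted over the list alone), with rpsQ, rplE (-2.27) and rpmC (-2.01) ahead. Their median was -0.47 and the adjusted p 0.000454 (adjusted p = 0.607 with an estimated correlation). Bacteriocins had 3 of 10 rise (4 adjusted over the list alone), SMU.423 (3.14), SMU.1906c (2.73) and nlmA (2.56). Their median was 1.15 and the adjusted p 0.0112 (adjusted p = 0.541 with an estimated correlation), which became 0.0804 without replicate 1 of glucose at pH 5. Their median was 1.88 without replicate 2 of glucose at pH 5 and 1.86 without replicate 1 of maltose at pH 5. The ribosomal list lost its call without replicate 1 of maltose at pH 5 (adjusted p = 0.0863).

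The other 20 lists had adjusted p-values from 0.157 to 0.998 at pH 5. Maltose, maltodextrin and glycogen use went both ways, with 4 of 13 genes rising and 3 falling (6 and 4 adjusted over the list alone, median 0.02), where malX and malQ rose and the glycogen synthesis genes glgD (-2.95) and glgB (-2.61) fell. Of the aminoacyl-tRNA synthetase genes 5 of 24 fell (7 fell and 1 rose adjusted over the list alone, median -0.39), with ileS at -1.98, thrS at -1.53 and pheT at -1.45. Pyruvate use had 3 of 15 fall (4 adjusted over the list alone, median -0.22), adhE, pfl (-1.64) and ackA (-1.09). Cellobiose, trehalose, mannitol and sorbitol use had treA and treB (-2.49, n = 3 in maltose) fall of 12 (2 adjusted over the list alone, median -0.23), and CRISPR-associated genes had csn2 (-2.62) and cas2 (-1.29) fall of 14 (2 adjusted over the list alone, median -0.11). A single gene rose in each of lactose and galactose use (lacB of 11, 1.38, n = 3 in glucose, 2 adjusted over the list alone, median 0.03), glycolysis (gapN of 11, 1.27, 1 adjusted over the list alone, median 0.17) and the citrate pathway (gdhA of 8, 1.66, 1 rose and 1 fell adjusted over the list alone, median -0.06). So it did in competence (comD of 15, 2.35, 2 adjusted over the list alone, median 0.18) and the mutanobactin cluster (mubG of 8, 2.19, 1 adjusted over the list alone, median -0.34). A single gene fell in each of the F-type ATPase (atpG of 8, -1.26, 1 adjusted over the list alone, median -0.18), glucan and adhesin genes (gtfC of 11, -2.43, 1 adjusted over the list alone, median 0.17), branched-chain amino acids (ilvD of 15, -1.35, 1 adjusted over the list alone, median 0.27) and pyrimidine synthesis (pyrF of 9, -1.44, 3 adjusted over the list alone, median -0.12).

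No gene was called at pH 5 between the sugars for malolactic fermentation (3, median -0.24), the agmatine deiminase system (3, 0.28), chaperones and proteases (15, 0.10), the msm operon (8, -0.34), purine synthesis (10, -0.18) and lipoteichoic acid D-alanylation (4, 0.31). The median and the test's direction had opposite signs for glucan and adhesin genes (mean -0.16) and the citrate pathway (mean -0.02, tested upward), and for the mutanobactin cluster camera tested downward and fry upward. Print-tip loess ended the calls of atpG (-0.68), trxB (0.93), lacB (0.34), gdhA (0.45), SMU.423 (2.05), SMU.1906c (0.996), cas2 (-0.71), rpmC (-0.75) and thrS (-0.59). It ended those of ackA (-1.08) and ahpC (1.247) as well, with changes closer to those above. Leaving out the pH 5 array of each sugar that correlated least with its group (replicate 1 of both) ended the list calls for fatty acid biosynthesis (adjusted p = 0.0812) and ribosomal proteins (0.187), and 25 of the 46 named genes that could be tested under all 31 alternatives were called under each. Pyruvate use passed the threshold with array weights (0.0357) and with subgrid medians subtracted (0.0348).

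**Figure D3:**
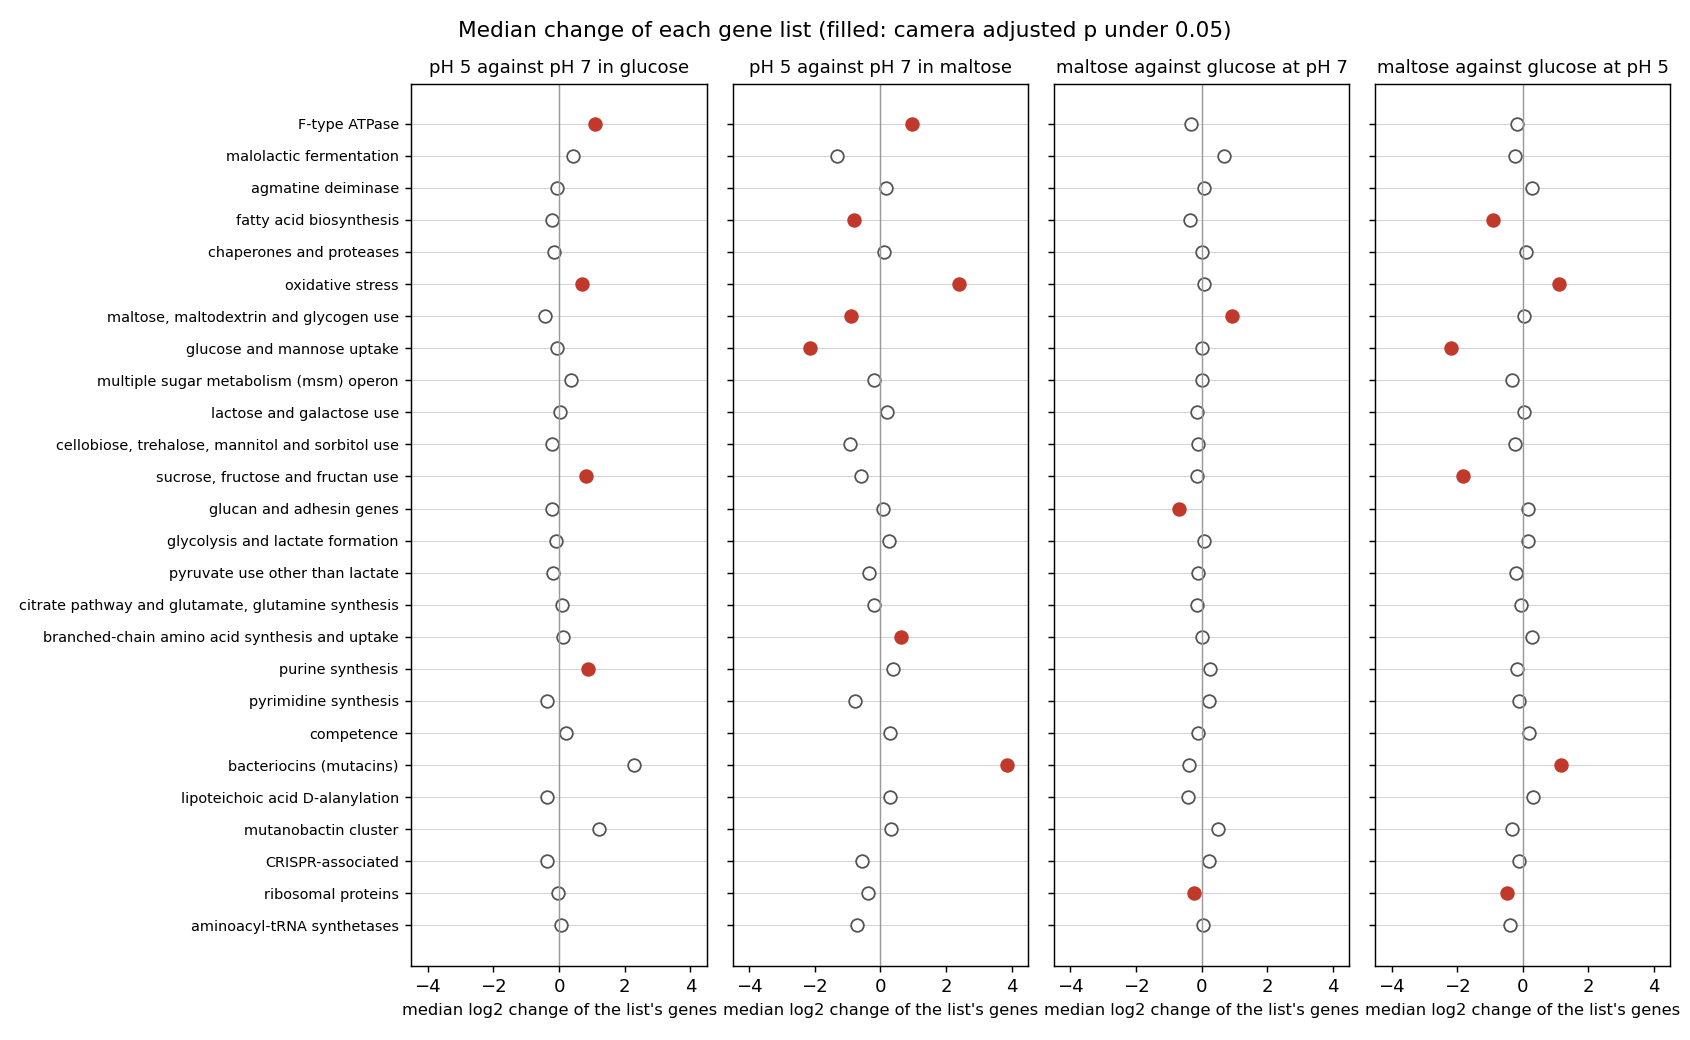
Median log2 change of the measured genes of each of the 26 lists in the 4 comparisons of groups, with filled points where the list's adjusted p (camera) was under 0.05. Glucose and mannose uptake lies at -2.14 for pH in maltose and at -2.19 for sugar at pH 5, and at -0.07 and 0.01 in the other comparisons.

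The difference of the pH effect between the sugars (maltose less glucose) asked whether the response to acid depends on the sugar. The genes treA, lrgA, lrgB, adhE and gabD fell with acid in maltose relative to glucose, and cidA rose. The pH effect of gabD was lower in maltose by a log2 difference of -4.10 ± 0.50 (17.1-fold, adjusted p = 0.000105), with means of 3.99 and 4.36 at pH 7 and pH 5 in glucose and of 4.31 and 0.58 in maltose (SD 0.43, 0.56, 0.29 and 0.53, n = 4 each). The differences were -4.63 ± 1.04 for lrgA, -4.56 ± 0.78 for treA, -4.39 ± 0.77 for lrgB and -4.24 ± 0.71 for adhE. In the other direction they were 3.99 ± 1.19 for SMU.1913c, 3.65 ± 0.68 for cidA (n = 3 in maltose at pH 7), 3.48 ± 0.96 for nlmA, 3.07 ± 0.79 for SMU.1903c (n = 3 in glucose at pH 5 and in maltose at pH 7) and 3.02 ± 0.78 for comD. The Cy3 signal of treA, SMU.1913c and comD was under the spot background on every array of at least 1 group. Of 1865 genes tested, 126 differed, 51 with a positive and 75 with a negative difference, all at least 2-fold. The count was 80 and 51 without replicates 1 and 2 of glucose at pH 7, and 69, 70 and 70 without replicates 2, 3 and 4 of maltose at pH 7.

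For 3 lists the difference of the pH effect passed the threshold. At least as many lists passed in 48 of 100 random regroupings of the arrays by sugar within each pH, the real grouping included. Glucose and mannose uptake differed in 5 of 6 genes, all negative (6 adjusted over the list alone), with a median of -1.97 and an adjusted p of 5.7e-07, and it passed with an estimated correlation (adjusted p = 0.0064). Sucrose, fructose and fructan use differed in 3 of 12, all negative (6 adjusted over the list alone), with a median of -1.60 and an adjusted p of 0.00216 (adjusted p = 0.0616 with an estimated correlation). With normexp background correction the median difference was 8.01-fold in place of 3.02-fold. Bacteriocins differed in 1 of 10, nlmA (4 adjusted over the list alone), and all 10 differences were positive. Their median was 1.78 (1.06 with array weights) and the adjusted p 0.00398 (adjusted p = 0.425 with an estimated correlation).

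The other 23 lists had adjusted p-values from 0.0862 to 0.879 for the difference. Negative differences were called in 4 of 24 aminoacyl-tRNA synthetase genes (6 negative and 1 positive adjusted over the list alone, median -0.57), 2 of 15 for pyruvate use (2 adjusted over the list alone, median -0.21) and 1 of 13 for maltose, maltodextrin and glycogen use (2 adjusted over the list alone, median -0.78). The same was called in 1 of 12 for cellobiose and related sugars (2 adjusted over the list alone, median -0.58), 1 of 10 for purine synthesis (1 adjusted over the list alone, median -0.60) and 1 of 9 for pyrimidine synthesis (1 adjusted over the list alone, median -0.41). Positive differences were called in 2 of 7 for oxidative stress (3 adjusted over the list alone, median 0.73), 2 of 11 for glycolysis (2 adjusted over the list alone, median -0.02) and 1 of 11 for glucan and adhesin genes (2 adjusted over the list alone, median 0.83). So were those of 1 of 15 chaperones (1 positive and 1 negative adjusted over the list alone, median -0.16), 1 of 15 competence genes (1 adjusted over the list alone, median 0.23), 1 of 8 for the citrate pathway (1 adjusted over the list alone, median -0.06) and 1 of 8 in the mutanobactin cluster (1 positive and 1 negative adjusted over the list alone, median -0.90). Fatty acid biosynthesis had 1 positive and 2 negative of 13 (1 and 3 adjusted over the list alone, median -0.52), and branched-chain amino acids 1 of each of 15 (the same adjusted over the list alone, median 0.40).

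No gene differed for the F-type ATPase (8, median -0.06), malolactic fermentation (3, -1.24, 1 negative adjusted over the list alone), the agmatine deiminase system (3, 0.26), the msm operon (7, -0.67), lactose and galactose use (11, 0.02), lipoteichoic acid D-alanylation (4, 0.55), CRISPR-associated genes (14, -0.32) and ribosomal proteins (51, -0.19). The median was negative and the mean positive, as was the test's direction, for the F-type ATPase (mean 0.07), glycolysis (0.14) and the citrate pathway (0.13). Print-tip loess called 61 genes in place of 126, with 24 in common, and ended the calls of SMU.1903c (1.71), comD (2.19) and adhE (-2.91), and those of SMU.1913c (3.52) and nlmA (2.92), whose differences stayed nearer to those above. It moved 5 of the 10 named genes by more than 1.5-fold, all to a smaller difference, with cidA at 2.47 and treA at -3.44. With subgrid medians subtracted the calls of comD (2.79) and adhE (-3.93) held, and those of SMU.1903c, SMU.1913c and nlmA ended. Scaling between arrays called 47 and ended those of lrgA (adjusted p = 0.19) and lrgB (0.293). The call of gabD held under each of the 31 alternatives, and those of treA and cidA under the 30 and 28 in which they could be tested. Print-tip loess brought the msm operon past the threshold (adjusted p = 0.026), and scaling the ribosomal proteins (0.0274). Aminoacyl-tRNA synthetases passed under 6 alternatives (0.0471 without replicate 2 of glucose at pH 5). Oxidative stress passed under 5 (0.0401 without replicate 1 of glucose at pH 5, 0.0382 without replicate 2 of maltose at pH 5).

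The pH responses in glucose and in maltose, which share no arrays, were set side by side for 1865 genes. Both were tested with the same estimate of each gene's spread, so their calls are not fully independent. The numbers expected of independent lists may therefore be too low. Of the 65 genes called in glucose and the 320 called in maltose, 27 were called in both, 15 rising in both (2.99 expected of independent lists), 11 falling in both (2.37 expected) and 1, ileS, going opposite ways (1.49 in glucose and -1.41 in maltose). Among the shared genes were SMU.1914c, SMU.1913c, SMU.1906c, tpx and SMU.602, which rose, and SMU.1895c, SMU.1896c, SMU.2146c and icd, which fell. Of the 65, 47 had the same sign in maltose, and across all genes, which are not independent replicates, the log2 changes had a Pearson r of 0.298 and a covariance of 0.23. With print-tip loess r was 0.528. The number shared was 14, 12, 13 and 17 without replicates 1, 2, 3 and 4 of glucose at pH 7. It was 12 without replicate 4 of glucose at pH 5, 17 without replicate 2, 3 or 4 of maltose at pH 7, and 39 without replicate 1 of maltose at pH 5.

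For the sugar responses at pH 7 and pH 5, 7 and 217 of 1865 genes were called and 2 in both. These were malQ, which rose in both (0.296 expected of independent lists), and rplX, which fell in both (0.067 expected). These expected numbers have the same limit as those for pH. The log2 changes had an r of -0.01 and a covariance of -0.0067 across genes, and r was 0.16 with print-tip loess. The number shared was 1 without replicate 1, 2 or 3 of glucose at pH 7, replicate 3 of glucose at pH 5, or replicate 1, 2 or 4 of maltose at pH 7, and 4 without replicate 1 of maltose at pH 5.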

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

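The tests of position on the slide, and those of subgrid effects and of 1 array for the glucose and mannose uptake genes, were chosen after the results they measure had been seen.

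The pH effect differed between the sugars for 126 genes, tested as a difference of differences with limma, and these include 44 of the genes named in the report. Subgrid accounted for 41.8% of the variance of this difference across genes, and print-tip loess kept the calls of 24 of the 126. Among the calls it ended were those of adhE, comD, nlmA, SMU.1903c and SMU.1913c. Negative log2 differences (lower in maltose) were -4.63 for lrgA, -4.56 for treA, -4.39 for lrgB, -4.24 for adhE, -4.10 for gabD, -3.62 for manM, -3.51 for recJ, -3.36 for pgmA, -3.24 for hisC, -3.21 for levF, -3.18 for the fruA of SMU.872, -3.12 for SMU.252 and -3.02 for manN. They were -2.92 for scrA, -2.90 for ileS, -2.77 for SMU.2147c, -2.60 for glgD, -2.58 for accA, -2.48 for thrS, -2.15 for pheT, -2.04 for glk, -2.02 for accC, -1.94 for ackA, -1.90 for manL, -1.75 for ilvD and -1.73 for pyrP. Among these genes, recJ had Cy3 signal under the spot background on 4 of 4 arrays of glucose at pH 7 and of maltose at pH 5. The same held for hisC on 4 of 4 arrays of glucose at pH 7. It held for levF on 4 of 4 arrays of glucose at pH 7 and of maltose at both pH values, and for treA, manN and glgD on 4 of 4 of maltose at pH 5. Positive differences were 1.31 for pyk, 1.49 for gapN, 1.51 for spaP, 1.80 for livH, 1.88 for ahpC, 1.97 for gor, 2.05 for SMU.995 (yclN), 2.09 for gdhA, 2.19 for fabH, 2.28 for gla, 2.37 for cidB, 2.50 for mubG, 2.74 for ftsH, 3.02 for comD, 3.07 for SMU.1903c, 3.48 for nlmA, 3.65 for cidA and 3.99 for SMU.1913c. Of these, the Cy3 signal of mubG was under the spot background on 4 of 4 arrays of glucose at both pH values and of maltose at pH 7. That of cidB was so in both glucose groups, those of comD and SMU.1913c in both pH 7 groups, and that of spaP in maltose at pH 7. For lists the median differences were -1.97 for glucose and mannose uptake, -1.60 for sucrose, fructose and fructan use and 1.78 for bacteriocins. In that order the lists had adjusted p = 0.0064, adjusted p = 0.0616 and adjusted p = 0.425 with an estimated correlation, so the last 2 calls ended there.

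The count of 126 genes was the largest of 100 splits of the arrays, with the real grouping as the only split as large (highest other 38). This argues against chance for the count as a whole. It does not do so for each gene, nor against effects of slide or day that go with the groups. Other splits mix the groups, so their counts do not give the number of false calls. No share below that of 1 split is possible, and the shares were not adjusted over the comparisons. The same holds for pH in glucose (65 genes, highest other 0 of 35 splits), pH in maltose (323, highest other 0) and sugar at pH 5 (219, highest other 29). For sugar at pH 7 the count was 7 genes (highest other 1). Chance is argued against for that count alone, as no splits were run for the alternatives. With normexp and without replicate 2 of glucose at pH 7, replicate 3 of glucose at pH 5, or replicate 1 or 4 of maltose at pH 7 the count was 1, as in the highest other split. For the number of lists chance could not be excluded. Counting the real grouping, at least as many lists were called in 6 of 35 splits for pH in glucose (4 lists, highest other 8), 2 for pH in maltose (7, highest other 7), 5 for sugar at pH 7 (3, highest other 3) and 4 for sugar at pH 5 (6, highest other 6). For the difference of the pH effect it was 48 of 100 splits (3 lists, highest other 8).

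On a single array, a named gene's log2 ratio lay far from those of the other 3 arrays of its group in 16 groups. In all 307 groups were tested, which include measures of the arrays as well as named genes, and chance gives about 1 in 20 (15.35). At pH 7 these were mleS on replicate 3 in maltose (1.51, others 2.62 to 2.79), glgD on replicate 1 in maltose (0.78, others 2.49 to 2.79), scrB on replicate 2 in maltose (2.28, others 1.44 to 1.52) and pyrB on replicate 1 in maltose (-0.61, others 0.35 to 0.46). Replicate 4 in glucose had rplX (-2.18, others -0.82 to -0.72), tpx (-0.68, others -1.85 to -1.68) and SMU.961 (5.38, others 4.43 to 4.56). At pH 5 in maltose they were atpD (0.41, others 1.00 to 1.11) and atpG (-0.053, others 0.86 to 0.92) on replicate 1, accA (-0.73, others -0.45 to -0.41) on replicate 2, trxB (1.247, others 0.81 to 0.85) on replicate 3 and ilvN (-0.046, others 0.24 to 0.28) on replicate 4. At pH 5 in glucose they were malX (-1.39, others 1.27 to 1.56) on replicate 1, gla (-2.19, others -1.25 to -1.14) on replicate 2, thrS (2.10, others 1.55 to 1.64) on replicate 3 and cidA (-0.53, others -1.57 to -1.55) on replicate 4.

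The glucose and mannose uptake genes were lower in maltose at pH 5 than in both neighbouring groups. Subgrid effects as the whole cause are argued against by print-tip loess, under which the higher of the list's medians was -1.59. A single array is argued against too, since the highest median with any array left out was -2.02. Effects of the slide or of the day that go with the groups cannot be excluded, as the labels give no batch and all arrays of a group may share one. A lower need for glucose uptake in acid maltose cultures stays open as a biological explanation and was not tested.

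Log2 ratios and changes differed between the subgrids of the slide. Position on the slide may be a source of this, since the deviations of single arrays from their group means, which hold no difference between groups, also differed between subgrids. On 16 of 16 arrays 16.8% to 45.8% of their variance lay between subgrids (highest random share 5.10%). Printing of neighbouring operon genes together is argued against, as 2.40% of 1747 pairs of neighbouring genes lay in 1 subgrid (2.08% by chance). The correlation of the subgrid medians between arrays had a median of 0.825 within maltose at pH 7, 0.0991 within glucose at pH 7, 0.399 within glucose at pH 5, 0.422 within maltose at pH 5 and 0.42 between groups, so only in maltose at pH 7 did the arrays share a pattern more closely. Printing cannot be separated here from other effects of position, and no biological explanation was tested.

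Arrays at pH 5 spread more around their group means than arrays at pH 7, with a ratio of the median SD of 1.551 (1.437 to 1.766 with each array left out). Lower mean intensity at pH 5 as the whole cause is argued against by the ratio at matched mean log2 intensity of both channels, 1.492 (1.313 to 1.728). The matching did not use signal over background, so it cannot decide on signal that was weak relative to background. Subgrid effects that differ between arrays could account for part, as the ratio was 1.299 after print-tip loess (1.221 to 1.419). For 1 poor array in each pH 5 group the ratio without them was 1.332 (1.173 to 1.517), and both stay open because these ranges reach below the limit set for excluding them. A greater spread of cultures at pH 5 is the biological explanation, and it was not tested.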

How the results depend on the processing

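Alternatives chosen after seeing the data were 1-channel flags left out, subgrid medians subtracted, and replicate 1 of both pH 5 groups left out together.

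The number of genes called stayed within 1.5 times under the other alternatives, and the values beyond that follow by setting. With normexp it was 13 (pH in glucose), 1 (sugar at pH 7) and 74 (difference of the pH effect), and the shared pH and sugar calls were 9 and 1. Scaling between arrays gave 136 (pH in glucose), 213 (pH in maltose), 2 (sugar at pH 7) and 47 (difference), with 5 lists for the difference, 0 shared sugar calls and a sugar correlation of 0.0988. Only the arrays compared gave 16 (pH in glucose), 21 (sugar at pH 7), 58 (sugar at pH 5) and 13 shared pH calls. That fit takes the spread from the groups compared alone. The median SD of a gene was 0.60 and 0.59 in glucose and maltose at pH 5, and 0.41 and 0.38 at pH 7. Fewer arrays as the whole cause is argued against by sugar at pH 7, where 7 calls became 21. Array weights gave 529 (pH in maltose), 248 (sugar at pH 7) and 203 (difference), with 7 lists for pH in glucose, 51 shared pH calls and 27 shared sugar calls. Print-tip loess gave 61 for the difference, correlations of 0.528 (pH) and 0.160 (sugar), 1 shared sugar call and a reversed oxdC change for pH in maltose (0.32). Subgrid medians subtracted gave 75 for the difference, correlations of 0.492 (pH) and 0.147 (sugar), and 1 shared sugar call. With 2 pH 5 arrays left out there were 27 genes for sugar at pH 7 and 42 shared pH calls. The ratios as deposited, median centring and the series matrix values each gave 1 shared sugar call, and the series matrix values and flagged spots kept gave 5 lists for the difference. The cause was not tested for these except where stated.

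With the replicate block 4 genes were called for sugar at pH 7, and 54, 280, 184 and 107 in the other comparisons. The numbers do not pair the arrays: correlations of deviations between arrays of the same number lay between -0.22 and 0.142.

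With each array left out in turn the counts ranged over 21 to 119 (pH in glucose), 217 to 388 (pH in maltose), 1 to 14 (sugar at pH 7), 154 to 243 (sugar at pH 5) and 51 to 154 (difference). Lists for pH in glucose ranged from 4 to 7 (7 without replicate 3 of glucose at pH 5), shared pH calls from 12 to 39 and shared sugar calls from 1 to 4.

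Of the named genes, 29 of 29, 65 of 66, 7 of 7, 51 of 51 and 10 of 10 kept their direction under the alternatives run for each, in the order of the report, the exception being oxdC. All 31 were run for 29, 60, 6, 46 and 7 of them, since genes with missing values could not be tested without some arrays. The higher and lower counts were 41 and 24 for pH in glucose. For sugar at pH 7, 6 higher and 1 lower became 6 and 0 as deposited and with median centring, 4 and 2 with print-tip loess, 1 and 1 with scaling, 121 and 127 with array weights, 14 and 7 with only the arrays compared and 17 and 10 with 2 pH 5 arrays left out. For the difference, 51 and 75 became 20 and 55 with subgrid medians subtracted.

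Signal over background limits calls of weak genes: 9.16% to 70.3% of background-subtracted Cy3 values per array lay below their own background (56.0%, 54.5% and 70.3% on replicates 1, 2 and 3 of maltose at pH 5, at most 44.4% on the others), with a median ratio of 0.746 to 2.36. A median of replicate spots was not run, since the files hold 1 value per gene, nor was a block for slide or scan date, which the files do not give.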

Other observations

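The genes and classes in this part were chosen after their values were seen.

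Genes of a pair of operons that act on cell lysis moved in opposite directions. In maltose at pH 5 against pH 7, lrgB fell 12.6-fold (SE 0.54), lrgA by a log2 change of -3.97 and the regulator gene lytR by -1.78 (SE 0.51), while cidA rose by 3.67 (SE 0.50) and cidB by 2.57 (SE 0.37). Against glucose at pH 5, lytR fell by -2.63 and lytS by -1.59, beside lrgA and lrgB, and cidA and cidB rose. None of the 6 was called for pH in glucose or for sugar at pH 7, and the difference of the pH effect was called for lrgA, lrgB, cidA and cidB. With print-tip loess the same counts, 2 rising and 3 falling for pH in maltose and 2 and 4 for sugar at pH 5, were called. For the difference of the pH effect print-tip loess called 1 positive and 4 negative of the 6, and cidB lost its call there (adjusted p = 0.0582), as it did with subgrid medians subtracted (0.0624) and with scaling (0.0889). Scaling also ended those of lrgA (0.19) and lrgB (0.293).

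The 4 genes of the ferrichrome transporter (SMU.995 to SMU.998), which takes up iron complexes, rose together. For pH in maltose their log2 changes were 2.06, 3.10, 1.42 and 2.94, and for sugar at pH 5 they were 2.41, 1.91, 1.87 and 2.18. None was called for pH in glucose or for sugar at pH 7, and the difference of the pH effect was called for 3 of them (2.05, 2.45 and 2.76). With subgrid medians subtracted the first of these, SMU.995, was 1.29 and lost its call (adjusted p = 0.169). The call of SMU.997 for pH in maltose ended with scaling between arrays (adjusted p = 0.06). In the bacteriocin region 10 of 13 genes rose and 2 fell for pH in maltose (11 and 2 with print-tip loess), and 3 rose and 2 fell for pH in glucose. SMU.1895c and SMU.1896c fell in both sugars, by -4.20 and -3.35 in glucose and -1.98 and -2.53 in maltose.

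Of the 32 functional classes in the files tested with camera, detoxification rose for pH in glucose (14 genes, 2 rose, median 0.56, adjusted p = 0.0446, and 0.38 with an estimated correlation). For sugar at pH 5, ribosomal proteins fell (56 genes, 15 fell and 1 rose, adjusted p = 0.00424, and 0.613 with an estimated correlation). Transport by phosphotransferase systems fell too (31 genes, 10 fell, median -0.20, adjusted p = 0.00424, and 0.039 with an estimated correlation), and its difference of the pH effect had an adjusted p of 0.0242 (0.0797 with an estimated correlation).

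A hypothesis was that subgrid effects hide changes that neighbouring genes share. The correlation of neighbouring genes' changes rose by more than 0.05 under print-tip loess in 4 of the 5 contrasts, from 0.356, 0.339, 0.0515, 0.319 and 0.167 to 0.406, 0.411, 0.134, 0.379 and 0.28. The rise is consistent with that hypothesis.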
